A study of Mus musculus with 4 samples.

How the data were processed

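Single-cell RNA sequencing was done on sorted mouse T cells (strain C57BL/6) with a droplet kit that tags transcripts at the 5′ end, and the labels describe 4 libraries in 2 groups of 2. The control group held CD8αα intraepithelial lymphocytes (IEL) from gut epithelium of mice with floxed Lrf alleles and no Cre (Cd4-Cre negative, Lrf fl/fl). The other group held CD8αα splenocytes from mice with floxed Lrf alleles and Cre under control of Cd4 (Cd4-Cre positive, Lrf fl/fl), called LRF knockout in the labels. LRF is the protein of the gene Zbtb7a. The sort gate in the labels excludes CD4 and requires CD45 and TCRβ, but names CD8β as both present and absent, so the CD8 part of the gate is not known from the labels. The labels do not say whether the replicates of a group came from separate mice. Xist and Y-linked UMIs show that they came from mice of different sex. Whether a library pools several mice is not known. The p-values measure the spread between these libraries, which includes sex.

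The deposited files are raw feature-barcode matrices of UMI counts (unique molecular identifiers, one per captured molecule), which the authors made with Cell Ranger 6.0.0 against the mouse genome build mm10. The files hold all barcodes, with no cells called and no values normalised in them. The annotation release behind the 32285 genes is not stated. Gene IDs and symbols come from the files, in which 40 symbols are shared by 2 gene IDs. Coordinates come from the GENCODE M21 annotation of mm10, in which all 96 named genes had a matching ID. The total was 9040267 UMIs for control IEL replicate 1, 31702790 for control IEL replicate 2, 36020618 for knockout splenocyte replicate 1 and 40155832 for knockout splenocyte replicate 2.

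Barcodes were called as cells per library above the 99th percentile of total UMIs of the top 3000 barcodes divided by 10, and never below 500 UMIs. The thresholds came to 835, 1453, 1356 and 1614 UMIs in control IEL replicates 1 and 2 and knockout splenocyte replicates 1 and 2. Barcodes with fewer than 250 genes or with more than 10% mitochondrial UMIs were left out. Scrublet (in scanpy 1.11.5, expected doublet rate 0.06) marked 9, 0, 0 and 1 barcodes, in the same order, as doublets. These were removed, but at 0.338% or less of the barcodes in each library the caller is taken not to have worked, so doublets remain. The cells kept were 2655, 5498, 8440 and 5338.

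Cells of all libraries were scaled to equal totals and log-transformed. Receptor and immunoglobulin segments, mitochondrial genes, Xist and Y-linked genes were taken out of the 2000 most variable genes, and the rest were reduced to 30 principal components. A graph of 15 nearest neighbours was divided with leidenalg 0.10.2 at resolution 1 into 23 clusters. A cluster was set apart from T cells if at least 2 of its 10 leading genes (after 20 CPM was added to each level) were markers of another lineage, or if its summed T cell transcripts lay below 0.5 of the median over clusters. A cluster led by epithelial genes that kept T cell transcripts was named T cells with epithelial transcripts. The limits of 2 genes and 0.5 were set after the clusters were seen. The remaining 18 clusters are called T-cell-like. Markers of NK cells or ILC did not count as another lineage, since T cells can hold them. Cluster 9, led by NK receptor genes, therefore stayed with the T cells, at 3089 CPM of summed T cell transcripts against 3094 in cluster 0. Markers were listed for T cells, gamma-delta T cells, conventional CD8αβ T cells, CD4 T cells, NK cells or ILC, B cells, plasma cells, macrophages with monocytes and dendritic cells, neutrophils, epithelial cells, erythroid cells, platelets, endothelial or stromal cells, and cycling cells. Shares of cells per library have exact Clopper-Pearson 95% intervals, and the limit of a share of 0 is 3 cells. Levels per cluster have exact Poisson 95% intervals. Both cover counting error only.

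UMIs were summed per library over T-cell-like cells, which gave 7379529, 25180419, 32303553 and 29718977 UMIs in the order above. The library was the replicate. edgeR 4.0.16 (R 4.3.3) was used with filterByExpr, TMM scaling, glmQLFit (robust) and the quasi-likelihood F test, 2 libraries against 2, with Benjamini-Hochberg adjustment over all tested genes at 0.05. Log2 fold changes are splenocyte minus IEL, and levels are CPM (UMI counts relative to the library total, after TMM scaling). Levels in clusters are CPM of the cluster's own total, without TMM scaling. Standard errors are those of the fitted log2 fold change. Because 1 coefficient carries both tissue and genotype, the comparison cannot assign a difference to either.

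The gene lists, the markers, the tests of genes, lists and shares and the rule for named genes were fixed before the data were examined. The tests of technical explanations were chosen after the results were seen. Named are Zbtb7a and Itgb7. Named too are the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among those with an adjusted p under 0.05, a mean log2 CPM of at least 6 and groups that do not overlap. That part of the rule leaves out receptor and immunoglobulin segments, mitochondrial, ribosomal protein, Xist and Y-linked genes, genes with clone names, and markers of other lineages. Of each list up to 4 members with the smallest adjusted p are named, and every member of the lists on homing and on recirculation. Not every gene the rule names is described. Other genes were chosen after their values were seen. The 17 lists covered gut homing and epithelial adhesion, lymphoid recirculation and naive or central memory, a natural IEL signature, cytotoxic effectors and chemokines, NK receptors and adaptors, tissue residency, lineage transcription factors, inhibitory receptors, cytokine receptors, TCR signalling and coreceptors, immediate early and stress genes, interferon response, cell cycle, aryl hydrocarbon receptor targets, glycolysis, oxidative phosphorylation and TGF-β response. Lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists. The same test with an estimated correlation and fry stand beside it. With an estimated correlation, camera works on the residual degrees of freedom of the fit, 2 here, so few lists could pass it. Marker lists with at least 2 tested genes were tested in the same way and adjusted among themselves. A gene at 0 in a group was compared with a floor of 3 counts summed over that group.

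Shares of T-cell-like cells with a UMI of 8 genes were computed as the expected share if each cell were thinned to 1000 UMIs, which leaves out cells with fewer. The shares were compared by an exact two-sided permutation test, which cannot go below 0.333 with 2 libraries against 2. B-cell-like cells of the splenocyte libraries serve as the measure of background.

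Simulated data with 12963 genes and the dispersions of these libraries were tested in the same way. Of 50 genes given a change of each size, 6 were recovered at 1.5-fold, 25 at 2-fold, 48 at 4-fold and 47 at 8-fold. Of 144 calls, 18 fell on unchanged genes, a larger share than the adjusted p threshold of 0.05 aims for.

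The alternatives were DESeq2 1.42.0 with its size factors, plain library-size scaling, no filter on low counts, at least 10 CPM in at least 2 libraries, the replicate number as a block, leaving out each library in turn, all called cells, a gate on cells with Cd8a and without Cd4 or Cd8b1, T-cell-like cells outside cycling clusters, a fixed minimum of 1000 UMIs per cell, doublets kept, subtraction of the profile of barcodes with 1 to 50 UMIs, thinning to the smallest library, an estimated correlation, cluster resolution 0.5 and thinning to 500 UMIs per cell. Leaving out the 6% of barcodes with the highest doublet scores, and leaving out 4 clusters low in UMIs or above 4% mitochondrial UMIs, were added after the data were seen, as was camera with plain library-size scaling. Where a library is left out, its group keeps 1 library, which is assumed to vary like the other group. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the rest.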

Results

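The series profiled CD8αα T cells of 2 origins, intraepithelial lymphocytes (IEL) from the gut of control mice and splenocytes from mice labelled LRF knockout, with 2 libraries each. LRF, the protein of Zbtb7a, is a transcription factor of T cell lineage choice. After cell calling, control IEL replicates 1 and 2 gave 2655 and 5498 cells with medians of 2673 and 4533.5 UMIs and 1311 and 1941 genes per cell. Knockout splenocyte replicates 1 and 2 gave 8440 and 5338 cells with medians of 3648 and 5301 UMIs and 1540 and 2023 genes. The median mitochondrial share was 1.99% and 1.98% in the IEL libraries and 1.91% and 2.39% in the splenocyte libraries. In control IEL replicate 1, 49.9% of the cells lay in a cluster led by AY036118, Lars2 and Gm42418, against 7.66% in control IEL replicate 2.

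T-cell-like cells made up 93.7% and 95.3% of the IEL libraries and 97.1% and 98.9% of the splenocyte libraries. Of them, 94.1% and 98.1% of IEL and 68.1% and 79.0% of splenocytes held a Cd8a UMI and none of Cd4 or Cd8b1. IEL cells lay mainly in clusters 2, 4, 6, 7, 8 and 15 and splenocyte cells in clusters 0, 1, 3, 5, 9, 10, 11, 12, 14, 17, 20 and 21. T cells with epithelial transcripts were 6.33% (exact 95% interval 5.43 to 7.32) and 4.71% (4.17 to 5.30) of the IEL libraries. None were seen in the splenocyte libraries, which allows a share of up to 0.0355% and 0.0562%. B-cell-like cells and cells like macrophages, monocytes or dendritic cells were seen in the splenocyte libraries and in neither IEL library, which allows up to 0.113% and 0.0546% there. For every class the exact two-sided permutation test could not go below 0.333.

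The comparison of the groups asks how the transcriptome of CD8αα splenocytes from these mice differs from that of gut CD8αα IEL. Tissue and genotype change together in it. The gene encoding LRF was higher, not lower, in the libraries labelled LRF knockout. Zbtb7a (ENSMUSG00000035011, mm10 chromosome 10, 81135220 to 81152995, plus strand, 3 exons in the transcript Zbtb7a-201) had 137 ± 17.1 CPM in IEL and 284 ± 5.06 CPM in splenocytes (mean ± SD, n = 2 libraries each). This is a 2.07-fold difference (log2 fold change 1.05, SE 0.17, edgeR adjusted p = 0.000145), and both splenocyte libraries (280 and 287 CPM) lay above both IEL libraries (125 and 149 CPM). The start codon lies in the second exon, 81143974, and 5′ tags fall near the start of transcripts, so they need not touch the deleted part, which the labels do not name. The value therefore tests neither the genotype nor the loss of the protein.

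Itgb7, the integrin β7 chain that pairs with integrin α4 or αE in homing to and retention in the gut, was lower in splenocytes. Itgb7 (ENSMUSG00000001281, mm10 chromosome 15, 102215995 to 102231944, minus strand) had 377 ± 27.9 CPM in IEL and 137 ± 4.05 CPM in splenocytes (mean ± SD, n = 2 each). It was 2.75-fold higher in IEL (log2 fold change -1.46, SE 0.17, adjusted p = 6.0e-06), with 357 and 397 CPM in the IEL and 140 and 134 CPM in the splenocyte libraries.

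Among splenocyte T-cell-like cells Itgb7 differed between clusters, which were singled out after their values were seen. In cluster 0, led by Ctla2a, Thy1 and Gramd3, it had 87.0 and 80.3 CPM (of the cluster's own UMIs) in replicates 1 and 2. In cluster 17, of 47 and 53 cells led by S100a4, Tmem176a and Tmem176b, it had 483 (exact Poisson 95% interval 397 to 582) and 467 (403 to 539). In cluster 20, of 8 and 20 cells led by Lgals1, Cx3cr1 and S1pr5, Itgb7 had 570 (326 to 926) and 623 (488 to 783). The IEL clusters 2, 4, 6, 7 and 8 held between 263 and 552. IEL cluster 15, of 31 and 169 cells with a median mitochondrial share of 5.43%, held 535 (331 to 818) and 769 (676 to 872).

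**Figure D1:**
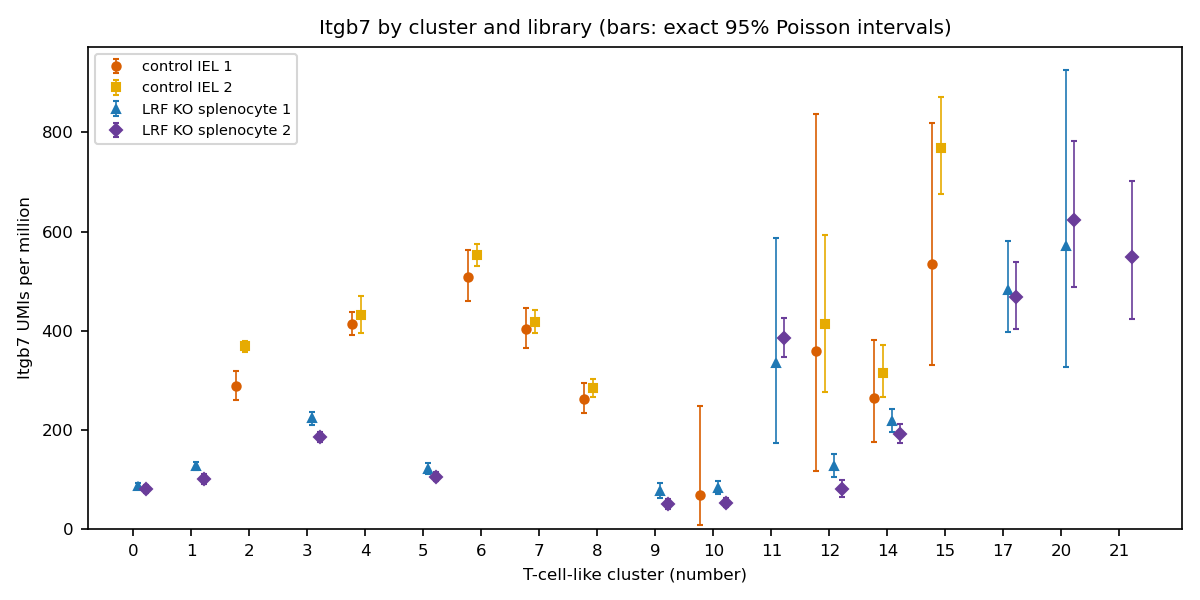
Itgb7 CPM in each T-cell-like cluster and library, with exact 95% Poisson intervals as bars. Splenocyte libraries reach the IEL range in clusters 17 (483 and 467) and 20 (570 and 623) and lie at 87.0 and 80.3 in cluster 0. Clusters 11 and 21, with median mitochondrial shares of 7.28% and 6.20%, are high as well, as is IEL cluster 15, at 5.43%.

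Of 12963 genes tested, 3014 were higher in splenocytes and 3031 lower, and 6918 did not pass. The change was at least 2-fold for 1694 of the higher and 1811 of the lower genes. The biological coefficient of variation between libraries of a group was 0.159. Across genes, which are not independent replicates, log CPM correlated at 0.978 between the IEL libraries, 0.989 between the splenocyte libraries and 0.823 to 0.846 between groups.

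**Figure D2:**
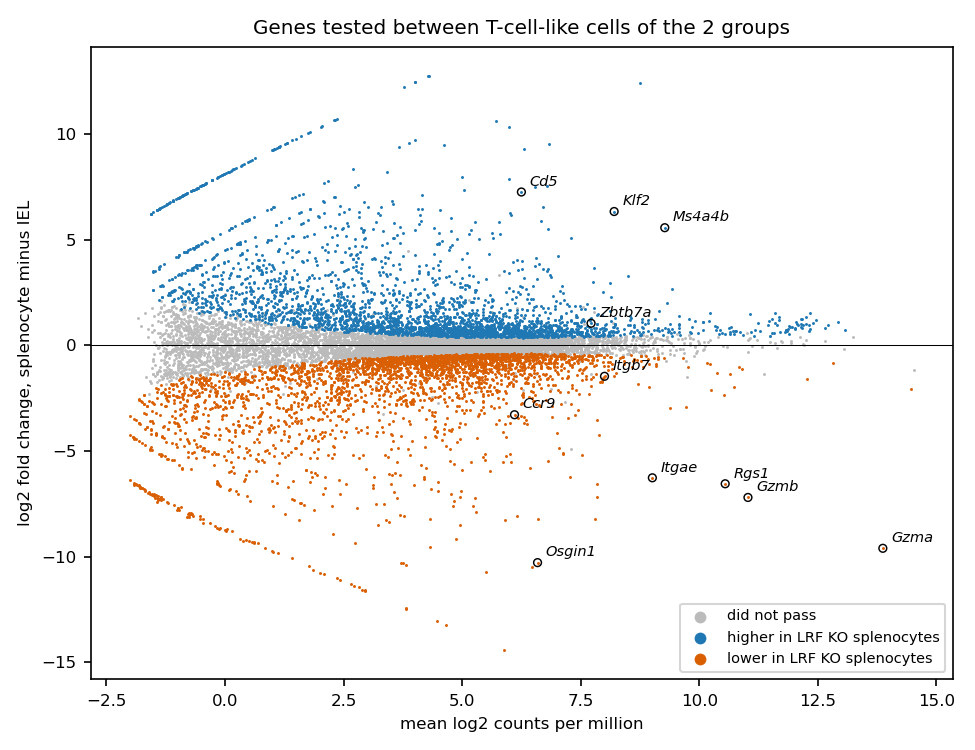
Log2 fold change (splenocyte minus IEL) of each tested gene against its mean log2 CPM, with genes higher and lower in splenocytes at adjusted p under 0.05 in colour (3014 and 3031 genes). The diagonal lines of points are genes with no or very few counts in 1 group, whose fitted fold changes depend on the prior count.

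The 10 genes with the largest differences upward included receptors and regulators of T cell circulation. Klf2, a transcription factor that drives expression of S1pr1, had 587 and 577 CPM in splenocytes and 2.84 and 10.2 CPM in IEL (log2 fold change 6.34). Cd5, an inhibitor of T cell receptor signals, had 154 and 145 against 1.03 and 0.937 CPM (7.27), and Ms4a4b had 1206 and 1216 against 18.2 and 31.7 CPM (5.58). Among the others were Cmah (9.32), Kbtbd11 (7.51), Gramd3 (6.57), Tspan32 (6.25), S1pr1 (6.19) and Ctla2a (5.92). All 10 had adjusted p of 0.00592 or less, the highest being that of Klf2.

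The 10 genes with the largest differences downward included 3 granule proteases and 2 integrin chains. Gzma, granzyme A, had 26289 and 33610 CPM in IEL and 18.0 and 58.7 CPM in splenocytes (log2 fold change -9.61, adjusted p = 0.0127), but its adjusted p was 0.103 without control IEL replicate 1 and 0.0996 without control IEL replicate 2. Gzmb, granzyme B, had 3461 and 4836 against 25.1 and 31.3 CPM (-7.20). Itgae, the integrin αE chain that binds E-cadherin on epithelial cells, had 1029 and 1014 against 10.3 and 16.2 CPM (-6.27). Osgin1 had 217 and 172 against 0.132 and 0.170 CPM (-10.29). The other 6 were Cd200r2 (-8.22), Fgl2 (-8.21), Gzmk (-8.10), Itga1 (-7.19), Dapk2 (-6.56) and Rgs1 (-6.55). The 9 other than Gzma had adjusted p of 0.000233 or less.

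Genes of gut homing and adhesion went both ways, with 10 of 14 lower and 4 higher in splenocytes. Among the lower were Itgae, Itga1 (integrin α1, a collagen receptor), Ccr9 (receptor of the gut chemokine CCL25, -3.28), Cd101 (-3.22), Gpr55 (-2.82), Jaml (-1.59), Itgb7 (-1.46), Gpr18 (-1.40) and Cxcr6 (-0.83). Higher were Gpr15, a homing receptor of the large intestine (5.26, 50.9 and 83.1 against 1.81 and 1.72 CPM), Itgb1 (2.80), the retinoic acid receptor gene Rara (1.94) and Itga4 (1.88, 239 and 286 against 60.2 and 81.1 CPM), the α chain that pairs with both Itgb7 and Itgb1. Adjusted over the list alone, the counts were also 4 higher and 10 lower. As a set the list was lower (camera adjusted p = 0.0493), but not with an estimated correlation (adjusted p = 0.70), nor without control IEL replicate 1 (0.0783) or replicate 2 (0.0888), with library-size scaling (0.0954) or after subtraction of free RNA (0.0503). Cxcr6 passed narrowly (adjusted p = 0.050) and missed the threshold in 13 of 18 alternatives.

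Genes of lymphoid recirculation and of naive or central memory T cells were higher in splenocytes throughout, with 15 of 15 past the threshold, also adjusted over the list alone. The transcription factors of the list rose, with Klf2 at 6.34, Lef1 at 5.09, Satb1 at 3.98, Klf3 at 3.87, Bach2 at 3.08, Tcf7 at 3.02 and Foxp1 at 1.17 on the log2 scale. So did the receptors S1pr1 (6.19), Il7r (3.96), S1pr4 (2.20), Cxcr3 (1.78) and Cd27 (1.71), and the integrin gene Itgal (3.56). Ccr7, the lymph node chemokine receptor, had 37.0 and 23.7 CPM in splenocytes and no UMI in IEL, which makes it at least 319-fold higher by a floor of 3 counts over the group. The median log2 fold change was 3.87, fitted or with Ccr7 at its bound. The set passed camera (adjusted p = 2.2e-09), but not with an estimated correlation (adjusted p = 0.428).

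**Figure D3:**
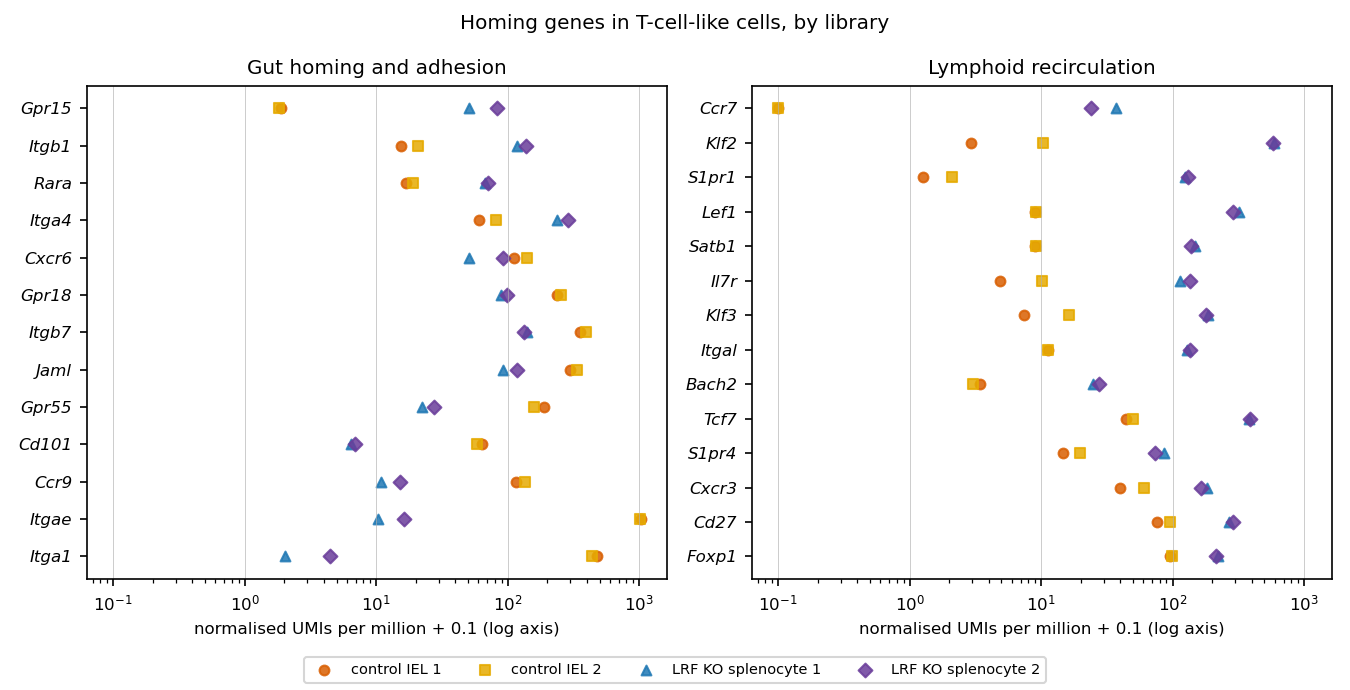
Normalised CPM plus 0.1 (log axis) of 13 genes of the gut homing list (left) and 14 of the recirculation list (right), with 1 symbol per library. On the right both splenocyte libraries lie above both IEL libraries for all 14 genes drawn, and on the left for 4 of 13.

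The natural IEL signature was largely lower in splenocytes, with 14 of 21 genes lower, 2 higher and 5 not past the threshold (16 lower and 2 higher adjusted over the list alone). Next to Itgae and Gzmb, its lower members included Hic1 (-4.35) and Entpd1 (-4.01, the ectonucleotidase CD39). Cd8a had 435 and 483 CPM in splenocytes and 1847 and 2076 CPM in IEL (-2.10). Higher were Il2rb, a chain of the receptors of interleukins 2 and 15 (1.12), and Zfp683, the transcription factor Hobit (2.48, under 9 CPM in all libraries). The set was lower (camera adjusted p = 1.6e-05, and 0.562 with an estimated correlation).

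Cytotoxic effectors and chemokines were lower in 12 of 17 cases and higher in 1, as they were adjusted over the list alone. Besides the granzymes A, B and K, Gzmc (-4.05), Prf1 (perforin, -2.59) and Ccl5 (-2.05, 33009 and 40022 against 8890 and 8753 CPM) fell, and Gzmm (2.64) rose. The set was lower (camera adjusted p = 7.0e-05, and 0.562 with an estimated correlation).

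Tissue residency genes were mostly lower, with 16 of 21 lower and 3 higher, also adjusted over the list alone. Prdm1, the transcription factor Blimp-1, had 60.9 and 53.5 CPM in IEL and 0.197 and 0.373 CPM in splenocytes (-7.62), Hpgds fell by 8.09 and Bhlhe40 by 4.40 on the log2 scale. The 3 higher genes were Zfp683, Ddit4 (1.77) and Nr4a1 (0.72). The set was lower (camera adjusted p = 1.6e-05, and 0.428 with an estimated correlation). The lists share members, Itgae being in 4 of them, so they are not separate pieces of evidence.

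Lineage transcription factors had no common direction, with 10 of 24 higher and 7 lower (9 lower adjusted over the list alone, camera adjusted p = 0.736). Myb (6.41, 44.3 and 43.6 against 0.516 and 0.508 CPM), Eomes (5.85) and Id3 (2.83) rose, and Prdm1, Zbtb7b (-3.07, the CD4 lineage factor ThPOK), Ahr (-2.47) and Runx3 (-1.33) fell. Zbtb7b was low everywhere, at 9.16 and 9.68 CPM in IEL and 1.18 and 1.05 CPM in splenocytes.

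NK receptors and adaptors were also divided, with 6 of 19 higher and 5 lower (6 lower adjusted over the list alone, camera adjusted p = 0.736). Without control IEL replicate 1, 10 were higher. Klrc2 (2.93), Klrc1 (2.83) and Klrk1 (2.18) rose, and Klra5 (-5.51) and the adaptors Tyrobp (-2.90) and Fcer1g (-2.36) fell.

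Inhibitory receptors were mostly lower, with 8 of 11 lower and 2 higher (9 lower adjusted over the list alone). Lilrb4a (-3.56) and Lag3 (-3.53, 462 and 390 against 28.4 and 45.5 CPM) fell, and Btla (5.85) and Pdcd1, encoding PD-1 (4.10, 53.3 and 63.6 against 3.35 and 3.44 CPM), rose. The set was lower (camera adjusted p = 0.0144, and 0.562 with an estimated correlation). Cytokine receptors went the other way in 11 of 20 cases, with 4 lower (5 adjusted over the list alone), but not as a set (camera adjusted p = 0.0812, and 0.0340 with all called cells). Il18r1 (24.7 and 18.3 CPM in splenocytes, 0 and 7 UMIs in IEL, with a fitted value of 6.68 that ran from 6.27 to 11.92 with a library left out), Il18rap (5.56) and Il10rb (1.66) rose, and Tgfbr3 (-2.37) fell.

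T cell receptor signalling genes and coreceptors were higher in 8 of 20 cases and lower in 7, also adjusted over the list alone (camera adjusted p = 0.564, with a median log2 fold change of -0.06, a mean of 1.13 and an upward test). Cd28 (65.9 and 62.1 CPM in splenocytes, 1 and 12 UMIs in IEL, with a fitted value of 7.37 that ran from 7.07 to 8.89 with a library left out), Cd5 (7.27), Ubash3a (4.64) and Cd2 (3.69) rose, and Cd3g (-1.97), Cd3e (-1.12) and Cd8a fell. Cd8b1 was higher in splenocytes (2.02) but low in all libraries, at 10.7 and 6.48 against 3.48 and 1.33 CPM.

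The TGF-β response list, whose genes include Itgae and Cd101, was lower in 8 of 11 cases and higher in 1, also adjusted over the list alone (camera adjusted p = 0.0128, and 0.428 with an estimated correlation). Ldlrad4 fell by 3.08 on the log2 scale and Smad3 rose (3.81). Of the aryl hydrocarbon receptor list, 3 of 3 measured genes were lower, also adjusted over the list alone (camera adjusted p = 0.00388, and 0.428 with an estimated correlation). They were Ahr itself (-2.47), Tiparp (-3.36) and Ahrr, which had 16.6 and 12.9 CPM in IEL and no UMI in splenocytes and was at least 291-fold lower there.

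Cell cycle genes were higher in 16 of 20 cases and lower in 1, also adjusted over the list alone (camera adjusted p = 3.5e-05, and 0.562 with an estimated correlation), with Ccnb2 (2.09), Ube2c (2.06), Tubb5 (2.01) and Birc5 (1.84) among them. The larger cycling cluster held 0.60% and 0.80% of the IEL libraries and 2.31% and 3.13% of the splenocyte libraries. Outside the cycling clusters the counts were 5 higher and 4 lower, and Ube2c, Ccnb2 and Birc5 changed sign without passing the test. Immediate early and stress genes were lower in 8 of 20 cases and higher in 6, also adjusted over the list alone (camera adjusted p = 0.0851). Hspa1a (-7.88), Hspa1b (-6.90) and Btg2 (-1.72) fell and Egr2 (1.80) rose, while Fos did not pass (172 and 435 against 16.5 and 4.04 CPM, adjusted p = 0.0974).

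Interferon response genes were higher in 9 of 21 cases and lower in 6 (12 higher adjusted over the list alone, camera adjusted p = 0.185), with Ifit3 (3.85), Usp18 (3.61) and Ifit1 (2.46) higher and Isg20 (-2.86) lower. Glycolysis genes were higher in 5 of 14 cases and lower in 1, also adjusted over the list alone (camera adjusted p = 0.159). Hk2 (2.01), Pgam1 (1.37) and Pgk1 (0.81) rose and Hk1 (-0.79) fell, and without control IEL replicate 2 there were 3 lower genes. Oxidative phosphorylation was the list with the fewest calls, 1 higher (Ndufa4, 0.98) and 1 lower (Ndufa13, -0.64) of 24, also adjusted over the list alone (camera adjusted p = 0.891, with a median of -0.07, a mean of 0.03 and an upward test). Ndufa13 missed the threshold without knockout splenocyte replicate 2 (adjusted p = 0.0727), 7 genes were higher without control IEL replicate 2, and 5 were lower without clusters low in UMIs or high in mitochondrial share. Atp5b (0.40, adjusted p = 0.0681) and Ndufa1 (-0.37, adjusted p = 0.0807) did not pass, but did so in 5 and 4 of 18 alternatives.

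**Figure D4:**
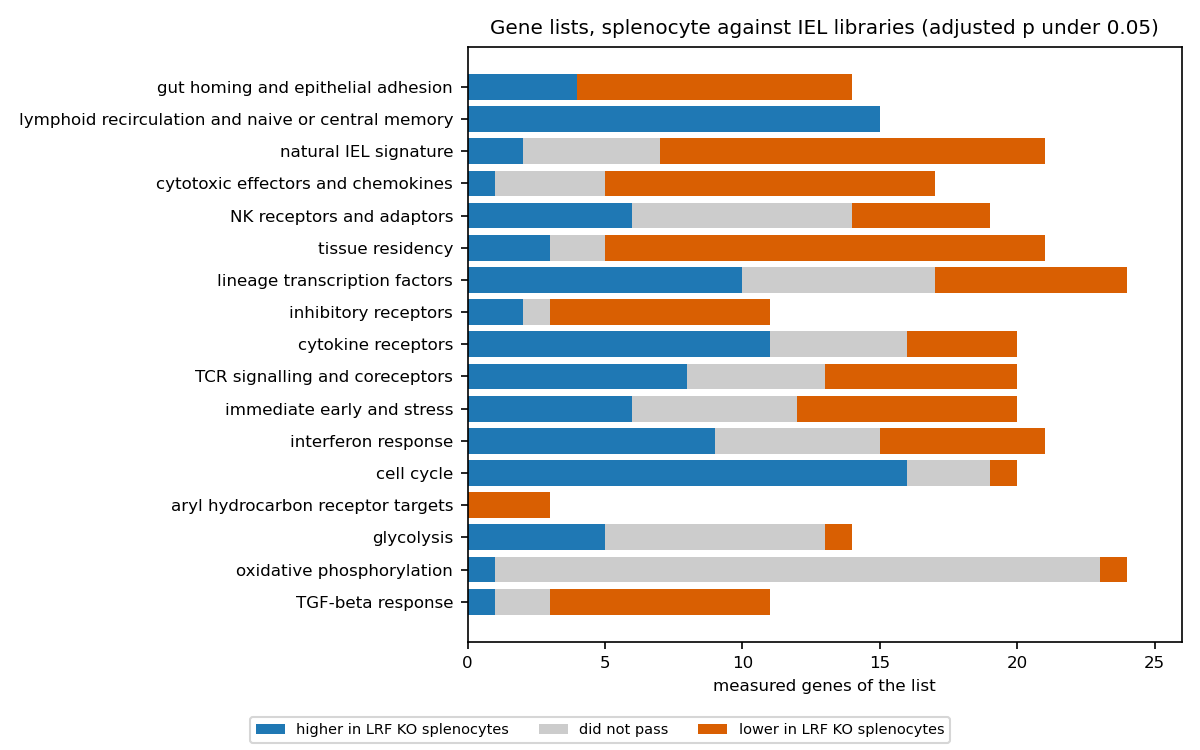
Number of measured genes of each list that were higher in knockout splenocytes, lower, or not past an adjusted p of 0.05. Of the recirculation genes 15 of 15 were higher, and of the tissue residency genes 16 of 21 were lower.

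Over the 17 lists, 9 passed camera with the preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.428 and 0 passed at an unadjusted p under 0.05. The aryl hydrocarbon receptor and TGF-β lists missed there (adjusted p = 0.428) although their estimates, -0.416 and -0.0823, lay below the preset 0.01. For these 2 lists a higher correlation between genes is therefore not the reason for the miss. In the other lists that passed with the preset value, the estimates ran from 0.0767 (tissue residency) to 0.650 (cell cycle). Correlation above the preset may account for those misses, but its part was not separated from that of the 2 residual degrees of freedom. By fry, which tests whether genes of a list move on balance in a common direction, 14 passed, the others being NK receptors, interferon response and oxidative phosphorylation. This count fell to 2 with the replicate number as a block, and it fell also with each library left out. Those fits have fewer residual degrees of freedom than the 2 of the main fit, and fry rests on them. The fall therefore does not show that the directions changed. All 17 passed fry's test of change in either direction, and 14 to 16 did so under the same alternatives.

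Markers of other cell types moved with these groups. Epithelial genes were lower in splenocytes in 17 of 17 cases (camera adjusted p = 2.2e-11, and 0.291 with an estimated correlation), with Epcam at 106 and 134 against 7.79 and 10.9 CPM and Cdh1 at 67.2 and 54.1 against 0.0658 and 0.136 CPM. They made up 0.0243% and 0.0247% of UMIs in IEL T-cell-like cells, and 0.0939% and 0.0882% of the free RNA there. The lowest marker of another lineage allows free RNA at most 1.44% and 0.641% of the UMIs of these cells. Free RNA can thus bring only a small part of their epithelial share. Among plasma cell genes 1 was higher and 3 lower, with Igha at 52.6 and 51.8 CPM in IEL and no UMI in splenocytes. B cell genes were higher in 3 and lower in 1 of 6 cases, macrophage, monocyte or dendritic cell genes higher in 2 and lower in 5 of 9 (median -0.57, mean 0.44, downward test), and the 1 measured erythroid gene, Hbb-bs, was higher. Of 2 endothelial or stromal genes 1 was lower, and no neutrophil or platelet gene was abundant enough to test.

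Markers of T cell types gave the following counts. General T cell genes were higher in 2 and lower in 4 of 10 cases, gamma-delta T cell genes lower in 3 of 6, and conventional CD8αβ genes higher in 5 of 6 with Cd8a lower. CD4 T cell genes were higher in 3 and lower in 1 of 4 cases, although Cd4 itself was too low to test. NK or ILC genes were higher in 6 and lower in 1 of 8 cases, and cycling genes higher in 7 of 8.

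Depth differed between libraries, so shares of cells with a UMI were compared at 1000 UMIs per cell, where 66 cells of control IEL replicate 1 were too shallow to enter. Cd8a was found in 82.7% ± 1.47 of IEL and 33.7% ± 2.70 of splenocytes (mean ± SD, n = 2 each). Itgb7 was found in 33.3% ± 0.94 and 12.0% ± 0.667, Itgae in 63.8% ± 1.18 and 1.12% ± 0.403, and Ccr9 in 12.0% ± 0.933 and 1.17% ± 0.363. Zbtb7a was found in 14.1% ± 0.906 of IEL and 24.6% ± 1.15 of splenocytes. For these genes, and for Cd8b1 (0.245% ± 0.139 and 0.759% ± 0.200) and Trdc (0.555% ± 0.137 and 0.419% ± 0.0146), the exact two-sided permutation p was 0.333, the smallest possible. Cd4 was found in 0.00252% and 0.00188% (exact p = 0.667).

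In B-cell-like cells of the splenocyte libraries (108 and 44 cells, median 3277 and 3811 UMIs, against 3638.5 and 5308 for T-cell-like cells there), Cd8a was found in 3.73% and 3.07% at the same depth. Cd8b1 was found in 0.125% and 0, Ccr9 in 0.0784% and 0, and Itgae, Cd4 and Trdc in none of these cells. Without thinning, none of 108 and none of 44 cells allow shares of up to 2.78% and 6.82%. The unthinned shares in splenocyte T-cell-like cells were 2.71% and 4.73% for Itgae and 1.22% and 1.61% for Trdc, under those limits, so the B-cell-like cells are too few to set them apart from background. For Cd8b1 (3.11% and 3.05%) and Ccr9 (2.83% and 4.81%) the 1 positive cell among 108 has an exact 95% interval of 0.0234 to 5.05%, and none of 44 allows 6.82%, which leaves the same doubt. B cells are not known to lack Zbtb7a (12.9% and 13.4%) or Itgb7 (5.93% and 6.31%), so these give no background. Between splenocyte clusters 0 and 3, picked after their values were seen, Itgae differed (1.27 and 31.9 CPM) and so did Ccr9 (1.78 and 31.3). An even background would not differ so, which argues against it for Itgae and Ccr9 in cluster 3. Cd8b1 (11.6 and 7.88) and Trdc (4.69 and 3.39) did not rise there, and their doubt stays.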

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

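The tests of depth, of RNA from other cells, of tag positions, of free RNA and of doublets were chosen only after the results they bear on were seen.

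Cells outside the T cell comparison were seen in the splenocyte libraries, in all but 1 case above the limit of 0.113% and 0.0546% that no such cells in the IEL libraries allow. B-cell-like cells, led by Cd79a, were 1.28% (exact 95% interval 1.05 to 1.54, 108 cells) of knockout splenocyte replicate 1 and 0.824% (0.600 to 1.10, 44 cells) of replicate 2. Cells like macrophages, monocytes or dendritic cells, led by H2-Ab1 and Cd74 or by Lyz2, were 1.29% (1.06 to 1.56, 109 cells) and 0.225% (0.116 to 0.392, 12 cells). A cluster low in T cell transcripts and led by Fscn1 and Ccr7, which no marker list named, was 0.367% of replicate 1 (31 cells), and 0.0375% of replicate 2 (2 cells), under those limits. The sort required TCRβ, which would remove these cells.

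Zbtb7a was 2.07-fold higher in the libraries labelled LRF knockout than in control IEL. Depth is argued against as the whole cause, since among T-cell-like cells of equal UMI count (bands of 2000 to 3000, 3000 to 4000 and 4000 to 5000) both splenocyte libraries lay above both IEL libraries, with exact Poisson 95% intervals apart. The ratio of the lower splenocyte to the higher IEL library was smallest in the last band, at 1.47 (250 and 170 CPM). RNA of other cell types is argued against too. Zbtb7a had 147 CPM in the B-cell-like cluster, up to 170 in clusters like macrophages, monocytes or dendritic cells, and 244 (exact Poisson 95% interval 167 to 344) in the cluster that no marker list named. These levels lay below the 264 and 285 CPM (without TMM scaling) of the splenocyte T-cell-like cells, so RNA at them could not raise Zbtb7a there. Among the upper limits of these clusters only 344 lay above, so the bound that follows adds to this only there. The leading genes of these clusters stood so low in splenocyte T-cell-like cells that RNA from them makes up at most 0.791% and 0.735% of the UMIs there. At the upper limits of Zbtb7a this brings at most 2.03 CPM, against the 112 CPM between the lower splenocyte and the higher IEL library. Tags from a part of the gene that was not deleted cannot be told apart from intact transcripts: the first exon, of 429 bp, lies before the start codon, and the files give no tag positions and the labels no deleted exon. The difference in tissue stays open as an untested biological explanation, as does the genotype.

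Barcodes with T cell and epithelial transcripts made up 6.33% and 4.71% of the IEL libraries. Free RNA alone is argued against, since epithelial genes took 0.630% and 0.295% of their UMIs, 6.71 and 3.34 times their share of the free RNA of the same library. Doublets with an intact epithelial cell cannot be told apart from T cells with attached fragments, since the median UMI count of these barcodes over that of other IEL T-cell-like cells was 1.09 in replicate 1 and 0.969 in replicate 2 and the doublet caller is taken not to have worked. T cell transcripts stood at 0.797 and 0.997 of their level in those cells. No cluster was named as epithelial cells alone in the main setting. A fixed minimum of 1000 UMIs gave 4 and 15 barcodes of that class in IEL replicates 1 and 2 (0.155% and 0.260%). What this means for doublets was not tested. The difference in tissue is the biological explanation the design names, and it stays untested.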

How the results depend on the processing

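Camera with plain library-size scaling, the omission of clusters low in UMIs or high in mitochondrial share, and the omission of the highest doublet scores were chosen after the data were seen. Of 105 values of the results that answer the comparison under alternatives, 97 stayed, 2 were weaker and 6 moved by more than the spread between libraries. To stay, Zbtb7a and Itgb7 had to keep their direction and side of the threshold. A count of genes or lists had to lie within 1.5-fold of the main count, and a share within the spread between libraries. The weaker values were counts, of higher genes at 10 CPM and of lists with an estimated correlation. Zbtb7a ranged from 0.92 to 1.18 and Itgb7 from -1.56 to -1.38 on the log2 scale, with adjusted p of at most 0.000726 and 5.9e-05. Large fitted log2 fold changes moved most with a library left out, with the direction kept. Il18r1, with few UMIs in IEL, ran from 6.27 to 11.92. Others were Klf2 (5.83 to 7.67), Tspan32 (5.27 to 6.99), Gzma (-10.65 to -8.96), Btla (4.97 to 6.35), Kbtbd11 (7.27 to 8.44) and Cmah (9.12 to 10.17). Smaller ones moved as well, such as Il7r (3.62 to 4.70), Klf3 (3.49 to 4.63) and Ubash3a (4.38 to 5.41). Leaving out each library in turn gave 2458 to 3210 higher and 2238 to 3065 lower genes, and 8 to 9 lists past camera. By fry's test of a common direction, which 14 lists passed, 2 passed with the replicate number as a block, and the count fell also with each library left out. Those fits have fewer residual degrees of freedom than the main fit, so a lower count need not mean changed directions. By its test of change in either direction, which all 17 passed, 14 passed with the block. The replicate number goes with the sex of the mice in both groups, so a block on it takes up sex too. With the replicate number as a block, the counts of genes higher in knockout splenocytes and genes lower in knockout splenocytes were 3134 and 3160. Same-numbered libraries of the groups deviated with a correlation of 0.212 across genes, and 0.0804 without Xist and Y-linked genes. With at least 10 CPM in at least 2 libraries, 1971 genes were higher, of 8430 tested. With an estimated correlation, 0 lists passed. That test put values of -0.416 to 0.65 in place of 0.01 and used 2 residual degrees of freedom. Correlation may explain the misses of lists with values above 0.01, but not those of the aryl hydrocarbon receptor and TGF-β lists. At 500 UMIs per cell the differences in share (splenocyte minus IEL, percentage points) moved from -48.9 to -41.7 for Cd8a, 0.513 to 0.267 for Cd8b1, -21.3 to -12.4 for Itgb7, -62.7 to -40.5 for Itgae, -10.8 to -5.73 for Ccr9 and 10.4 to 5.83 for Zbtb7a. Fewer UMIs per cell lower each share, but need not shrink a difference, which for Cd8a was -20.8 without thinning. Without cycling clusters Ube2c (-0.57), Ccnb2 (-0.53) and Birc5 (-0.44) reversed without passing (adjusted p 0.317, 0.442 and 0.493), as the cells that hold most of these transcripts were left out. Of 2302 values of named genes and list counts, 2255 stayed by the same rules, 21 were weaker, 23 stronger and 3 reversed. For a gene, weaker or stronger means that it lost or gained the threshold, and for a list that its count changed by more than 1.5-fold. DESeq2 kept 5109 of 6045 calls with the same sign, and gave no adjusted p for 4845 genes. Of these calls, 26 changed sign with all called cells and 32 without cycling clusters. Library-size scaling moved the median log2 fold change by -0.09 and left 43.1% of calls upward, against 49.9%. With 2 libraries per group, the simulated data recovered 6 of 50 genes changed 1.5-fold. The simulation changed far fewer genes than the 6045 called in the data, so its threshold was stricter and this rate does not carry over. Small differences can be missed with 2 libraries per group, at a rate that is not known. Of the 144 calls in the simulated data, 18 fell on unchanged genes, a larger share than the adjusted p threshold of 0.05 aims for. The threshold was thus not held there. Calls in the data, above all those near the threshold, may include more false ones than it implies, at a rate that is not known either.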

Other observations

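The clusters and genes of this part were chosen after their values were seen, and no differences between them were tested beyond the adjusted p given. Splenocyte T-cell-like cells held several clusters that the comparison of the groups averages over. Cluster 3, led by Tnni1, Tsc22d1 and Pdcd1 and with Sox4 and Gpr15 among its leading genes, held 1181 and 1099 cells of knockout splenocyte replicates 1 and 2. Cluster 9, led by the NK receptor genes Klrb1c, Klrk1 and Klrc1 and with Eomes among its leading genes, held 372 and 415 cells (4.41% and 7.77%). Cluster 10, led by Nr4a1, Egr1 and Xcl1, genes induced by T cell receptor signals, held 400 and 315 cells (4.74% and 5.90%). Cluster 11, led by Itga4 and Sptbn1, held 0.273% and 8.15%, with a median mitochondrial share of 7.28%. Cells with a Klrg1 UMI, 3 and 16 in number, had Itgb7 at 400 (exact Poisson 95% interval 183 to 759) and 800 (615 to 1023) CPM, against 131 and 131 in cells without, and 2 and 11 of them lay in cluster 20.

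Receptor segments differed between the groups. Of 11 measured γ chain genes 9 were lower in splenocytes and 0 higher, with Tcrg-C1 at 164 and 105 against 11.6 and 13.4 CPM and Trgv2 at 695 and 871 against 177 and 226 CPM (adjusted p = 1.9e-07 and 1.7e-06). The γ genes are alike in sequence, and reads shared between them were not tested. Of 4 δ chain genes none passed, with Trdc at 7.48 and 4.84 against 5.03 and 3.83 CPM. Of 23 Trbv genes 11 were higher and 1, Trbv4, lower, and of 67 Trav genes 18 were higher and 3 lower. Trbv31 (2.10 on the log2 scale), Trbv12-2 (1.74), Trbv17 (1.57) and Trbv3 (1.45) were among the higher ones.

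Ly6c2, which the rule for named genes leaves out as a monocyte marker, had 947 and 765 CPM in splenocyte T-cell-like cells and 0.258 and 0.117 CPM in IEL (12.41 on the log2 scale). Replicate 1 of each group held UMIs of the Y-linked genes Ddx3y (50.2 CPM in IEL, 39.8 in splenocytes) and Eif2s3y (83.7 and 68.4) and none of Xist. Replicate 2 of each group held Xist (590 and 782 CPM) and no UMI of those genes. Each group thus held 1 library from male and 1 from female mice, and the replicate number stands for sex in both groups.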
